A study of Homo sapiens with 31 samples.

How the data were processed

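Gene expression was measured on Affymetrix Human Gene 1.0 ST arrays, which read each transcript with several short probes spread along it. The RNA came from tumours of the human prostate carcinoma line PC3 grown as xenografts, and total RNA was extracted with Trizol and labelled with biotin, per the labels' protocols. The deposited table held 23989 probe sets on 31 arrays. Its values were log2 expression levels made with RMA, per the submitters' processing notes; RMA corrects the background, forces the arrays to a common distribution and summarises the probes of a set. The RMA software and version were not given in the sources used here. The deposited log2 values ran from 1.27 to 14.1. The array medians lay between 6.59 and 6.73, and the interquartile ranges of the arrays between 2.64 and 3.02. The design text planned 32 arrays, of which the submitters left out 1 as an outlier; it was not analysed here. That array was untreated and of clone A3, so 7 groups held 4 arrays and 1 group held 3.

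Probe sets were named with the platform annotation. Of the probe sets, 17624 carried 1 gene symbol, 411 carried several and 5954 carried none, and only those with 1 symbol were named. For the 276 genes with more than 1 probe set, the set with the highest mean over all arrays was kept, which left 17314 genes. The Entrez numbers of 17290 of these were found in a RefSeq gene table for the assembly GRCh38.p14, which was used only for current names, for older names in the gene lists and for which genes neighbour each other. Other probe sets of the same gene sometimes gave another value: UHRF1 differed by 0.87 between A3 and wt on the set used and by 0.02 on the other, and ALDH1A3 by 0.38 and -0.05.

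Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) in 1 fit over all 31 arrays, with a mean for each of the 8 groups of line and treatment. The groups then share 1 estimate of the spread per gene, with 23 residual degrees of freedom. P-values were adjusted over all genes by the Benjamini-Hochberg method and a gene was called at an adjusted p under 0.05. Values in the text are log2 differences with their standard error from this fit (SE), or group means with the SD over arrays. The median residual SD over genes was 0.148, which gives a difference between 2 groups of 4 arrays a standard error of 0.105. The number of arrays limits the precision. The labels speak of xenografts and replicate numbers and do not say outright that each array held the tumour of another animal, so the p-values measure the spread between these samples, part of which may be technical.

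There were 31 gene lists of pathways, cell types and controls, written before the data were examined, with 738 genes of which 634 were measured. The 30 lists with at least 5 measured genes were tested with camera in limma, which compares a list with all other genes, at a preset correlation between genes of 0.01 and again with the correlation estimated from the data. Adjusted p-values of lists were taken over the lists tested in that comparison. Lists of mouse host cells were included because a human array can bind RNA of the host. The genes named in the text followed a rule also written before the data were examined. For the resistant clones against A3, for A3 against wt and for CPA in each line, it took the 12 genes with the highest and the 12 with the lowest log2 difference among called genes whose arrays did not overlap between the sides. To these it added up to 4 members of each list with the smallest p, and for the other comparisons the 5 genes with the smallest adjusted p in each direction.

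The alternatives fixed before the data were examined were a fit of only the groups compared, the replicate number as a block, a trend of the variance with expression, array weights, a further quantile normalization, centring on each array's median, leaving out the dimmest 30% of genes, all probe sets, each array left out in turn, the line as a random block, and wt in place of A3. The 12 results were also computed without the 4 arrays that lay farthest from their group mean and, for the overlap of D3 and D4, without shared arrays; both were chosen after seeing the data. The labels give no scan dates or batches, and none was used here.

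The fit was tested on simulated data built from the real gene means and spreads, with 200 of 17314 genes changed. At a log2 change of 1 it recovered 100% of them for CPA in wt, 100% for CPA in A3, 99.0% for A3 against wt, 100% for the resistant clones against A3 and 100% for the comparison of the CPA effect between resistant and sensitive lines. At a log2 change of 0.5 it recovered 76.0%, 65.0%, 70.0%, 78.0% and 74.0% in the same order. The genes of the mitosis list were lowered as well. Of the genes left unchanged 9, 11, 6, 9 and 12 were called in the same order. These simulations hold no correlation between genes or arrays.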

Results

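Total RNA of PC3 tumours was profiled on 31 arrays in 8 groups. PC3 is an established human prostate carcinoma cell line that lacks functional p53. The lines compared were the unpassaged parental line (wt) and 3 clones re-isolated after passage in animals, A3, D3 and D4. The labels call wt and A3 sensitive, and D3 and D4 resistant, to cyclophosphamide (CPA), a prodrug that is activated in the liver and crosslinks DNA. Each line was implanted again, and when the tumours averaged 30 mm3 some animals received CPA at 120 mg/kg intraperitoneally and the others served as controls. Each group held 4 arrays except untreated A3, which held 3. The series concerns resistance to metronomic CPA, the repeated giving of low doses without long breaks. Replicate arrays correlated at 0.985 to 0.997 across genes. The first principal component carried 28.5% of the variance, and untreated wt averaged -21.0 ± 7.87 (SD, n = 4) on it against 8.02 ± 13.1 (SD, n = 3) for untreated A3.

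The central question was how the resistant clones differ from A3, which had also been passaged in animals but stayed sensitive. In untreated tumours DHRS2, a short-chain dehydrogenase/reductase, was 4.06-fold higher in the resistant clones (log2 difference 2.02 ± 0.10 SE), and PASD1, a cancer/testis antigen, was 3.93-fold higher (1.98 ± 0.10 SE). Neurotensin (NTS) was 5.05-fold lower (-2.34 ± 0.21 SE), and TCN1, a vitamin B12 binding protein, was 2.60-fold lower (-1.38 ± 0.14 SE). Their adjusted p-values were 2.6e-14, 2.6e-14, 1.8e-08 and 9.0e-08, and for each of these genes all 8 resistant arrays lay beyond all 3 A3 arrays. Such a lack of overlap was a condition for naming them, and 856 of 17314 genes (4.94%) met it. In all, 673 of 17314 genes were called, 320 higher and 353 lower, and 13 of them differed at least 2-fold. The resistant arrays came from clones D3 and D4 and the others from the single clone A3. The p-values thus measure the spread within these clones and cannot separate resistance from other differences between them.

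**Figure D1:**
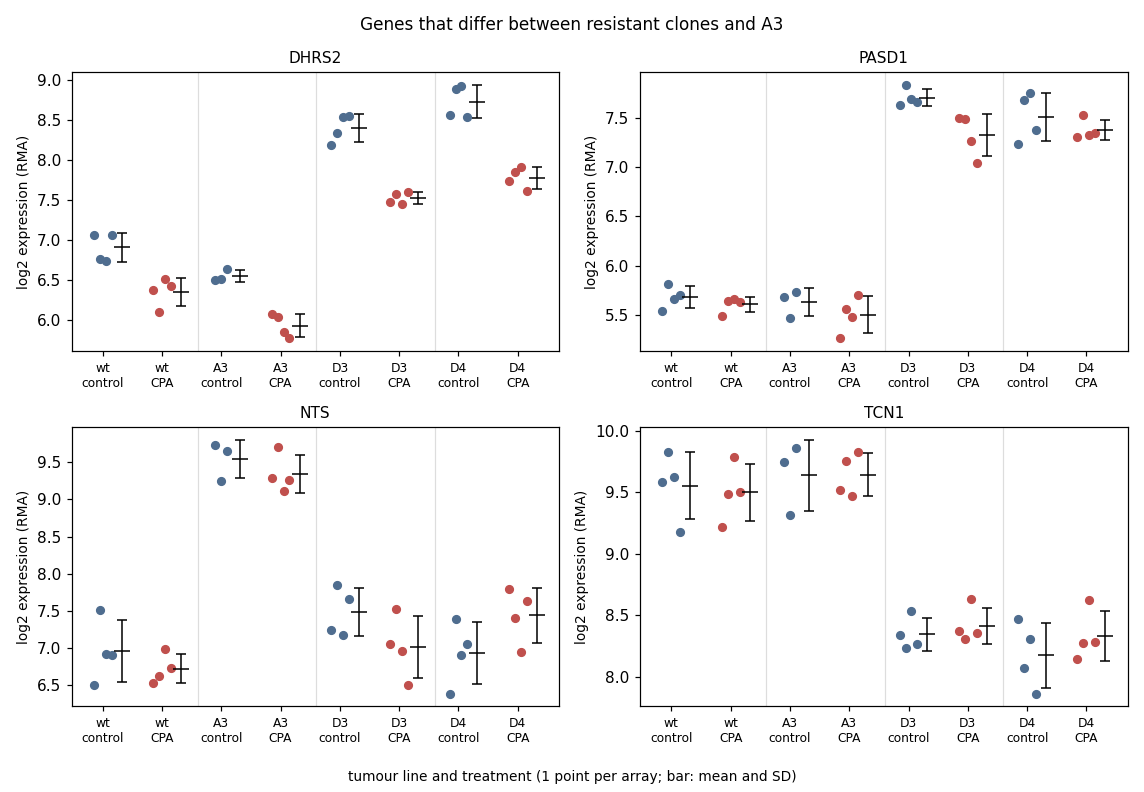
Log2 expression of DHRS2, PASD1, NTS and TCN1 (vertical axes) on each array of the 8 groups of line and treatment (horizontal axes; blue control, red CPA; black bars mean and SD). DHRS2 averaged 8.40 and 8.73 in untreated D3 and D4 against 6.55 in A3 and 6.91 in wt, while NTS averaged 9.54 in untreated A3 and between 6.93 and 7.48 in the other untreated lines.

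The other genes that rose most in the resistant clones were F3, the tissue factor that starts coagulation (1.16 ± 0.14 SE), the kinase STK26 (1.10 ± 0.12 SE), the zinc finger genes ZNF626 (1.09), ZNF788P (0.96) and ZNF486 (0.94), CDC20B (1.02), the urea transporter SLC14A1 (2.00-fold), the chromatin organiser SATB1 (0.96), MPZL2 (0.92) and MBNL3 (0.92). Those that fell most were the decoy receptor IL13RA2 (-1.22 ± 0.18 SE), the cancer/testis antigen MAGEC2 (-1.19 ± 0.12 SE), HCLS1 (-1.12), IL1RAPL1 (-1.03), SCN3A (-0.93), the bone morphogenetic protein receptor BMPR1B (-0.92), SERPINB7 (-0.91), podoplanin (PDPN, -0.86), SH2D1B (-0.84) and SSX8P (-0.83). Set against wt instead, a check chosen after seeing the data that uses the same resistant arrays, 243 of the 673 genes were called the same way, 85 the opposite way and 345 not at all. Of the genes named so far DHRS2, PASD1, F3, STK26, ZNF486 and MBNL3 were higher and TCN1, HCLS1, IL1RAPL1 and BMPR1B lower than wt too. SLC14A1 was lower than wt (-0.92 ± 0.13 SE), MAGEC2 (0.36) and SERPINB7 (0.57) were higher, and the others were not called. By clone, MAGEC2 differed from wt by only 0.02 in D3 (adjusted p 0.962) and SERPINB7 by only 0.08 in D4 (adjusted p 0.695). The rise of F3 came mostly from D4. Untreated, F3 averaged 8.93 in D4 and 7.41 in D3, against 7.01 in A3 and 7.09 in wt. In untreated wt NTS averaged 6.96 ± 0.41 (SD, n = 4), whereas TCN1 averaged 9.55 ± 0.27 (SD, n = 4) in wt and 9.64 ± 0.29 (SD, n = 3) in A3.

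Among the fixed lists, sterol synthesis genes were lower in the resistant clones. Of 19 measured members 8 fell, 0 rose and 11 did not pass, and 16 fell when adjusted over the list alone. NSDHL (-0.41 ± 0.07 SE), MVK (-0.39), FDPS (-0.37) and HMGCS1 (-0.38) were the clearest. Against wt HMGCS1 was called lower too (-0.41), but NSDHL (0.05), MVK (-0.07) and FDPS (-0.12) were not called. In A3 itself 6 of the 19 were called higher than in wt and 0 lower, whereas in D3 5 and in D4 6 were called lower than in wt and 0 higher. The list's median was -0.30 and its adjusted p was 7.3e-14, against an adjusted p = 0.0594 with an estimated correlation. Of 36 DNA replication genes 5 fell (CDC45 -0.38, MCM5 -0.36, MCM2 -0.29, RRM1 -0.33; CDC45, MCM5 and MCM2 were higher than wt by 0.56, 0.48 and 0.38), or 7 when adjusted over the list alone with 1 rising, and the list's adjusted p was 0.00341, but adjusted p = 0.873 with an estimated correlation. None of 35 mitosis genes was called, also when adjusted over the list alone, although 33 were lower and the list's adjusted p was 0.00126 (adjusted p = 0.873 with an estimated correlation). Of 25 glutathione genes 3 fell, GSTT1 (-0.48), GSTM3 (-0.52) and GSTM4 (-0.40), or 9 with 1 rising when adjusted over the list alone (adjusted p 0.0131 for the list, and adjusted p = 0.639 with an estimated correlation). Of 30 genes of the integrated stress and unfolded protein response 3 rose, SLC7A5 (0.57), ASNS (0.40) and STC2 (0.45, but -0.68 against wt), and SDF2L1 fell (-0.43). When adjusted over the list alone 4 rose and 3 fell, and the list had an adjusted p of 0.0462 (adjusted p = 0.799 with an estimated correlation). Its direction turned with the reference line. Against wt its median was -0.18 in D3 (13 genes fell, 5 rose) and -0.25 in D4 (14 fell, 4 rose).

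Besides the glutathione list given above, lists that bear on how CPA is handled held few called genes in this comparison. Few genes were called at all (673 of 17314), so low counts in short lists do not show that drug handling was unchanged. None of the 4 measured members of the list for activation or deactivation of CPA was called. These were the cytochrome P450 genes CYP2B6, CYP2C8 and CYP3A5 and the reductase gene POR, and CYP2C8 (-0.46, adjusted p 0.0574) was the closest. Of 19 aldehyde dehydrogenases, several of which oxidise the intermediate aldophosphamide, only ALDH18A1 passed (-0.32, adjusted p 0.0061), with 3 lower when adjusted over the list alone. None of 35 genes for repair of alkylated or crosslinked DNA and none of 12 drug efflux transporters was called. When adjusted over the list alone the repair list had 0 calls and the transporters 1, which was higher. In the list of genes induced by NRF2 the malic enzyme ME1 rose (0.72 ± 0.08 SE) while TALDO1 (-0.32) and HMOX1 (-0.41, but 0.26 against wt) fell. Among 28 epithelial genes 4 rose, DSP (0.53, but -0.34 against wt), KRT8 (0.58), EPCAM (0.32) and PKP2 (0.25), with an adjusted p of 0.216 for the list. None of the host-cell lists (fibroblast, endothelial, myeloid, erythroid, muscle, adipocyte, skin) was called. The fibroblast list came closest, with a median of 0.10 and an adjusted p of 0.0609, and the 25 lists not called had adjusted p-values up to 0.940.

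The 3 untreated A3 arrays carry this comparison: without A3 replicate 4 the count was 268 and without A3 replicate 1 it was 375. A fit of only the 3 groups compared called 237 genes, and array weights gave 1782. Of 100 splits of the same arrays, 1 other than the real one called more genes, 2476.

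Each resistant clone was also set against A3 by itself. D3 differed in 393 genes, 225 higher and 168 lower, led by PASD1 (2.07 ± 0.12 SE), DHRS2 (1.86 ± 0.12 SE), STK26 (1.40), ZNF626 (1.18) and GPC4 (0.95) on the higher side and by PDPN (-1.06), MAGEC2 (-1.53), HCLS1 (-1.02), NTS (-2.06) and TCN1 (-1.29) on the lower. D4 differed in 653 genes, 303 higher and 350 lower, with DHRS2 (2.19 ± 0.12 SE), F3 (1.92 ± 0.16 SE), PASD1 (1.88), PRSS35 (1.23) and ME1 (0.97) higher and NTS (-2.61), SERPINB7 (-1.40), HCLS1 (-1.23), PDE3A (-1.07) and the muscarinic receptor CHRM3 (-0.98) lower. The sterol list was lower in both, with adjusted p 4.0e-15 in D3 (adjusted p = 0.0406 with an estimated correlation) and 3.4e-09 in D4 (adjusted p = 0.278 with an estimated correlation). In D3 the fibroblast markers were higher by a median of 0.08 (adjusted p 0.0312, and adjusted p = 0.322 with an estimated correlation). Also called in D3 were mitosis (0 of 35 genes called, lower, adjusted p 0.00766), DNA replication (3 of 36 fell, or 5 when adjusted over the list alone, 0.00288), the stress response list (2 of 30 rose and 1 fell, higher, 0.0343) and stem and progenitor markers (3 of 16 rose, or 4 with 1 falling when adjusted over the list alone, 0.0343). With an estimated correlation these had adjusted p = 0.869, 0.786, 0.786 and 0.121. Against wt D3 went the other way for 3 of them: the stress response list was lower (median -0.18), and mitosis (0.51) and DNA replication (0.46) were higher. In D4 the others were glutathione (6 of 25 fell, or 8 when adjusted over the list alone, adjusted p 0.00303), mitosis (0 of 35 called, lower, 0.0024), DNA replication (1 of 36 fell, or 5 with 1 rising when adjusted over the list alone, 0.0272) and ribosomal protein genes (0 of 22 called, lower, 0.0455), with adjusted p = 0.740, 0.943, 0.952 and 0.943 with an estimated correlation.

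With only the groups compared D3 differed from A3 in 105 genes and D4 in 67, and in D4 the number of higher genes, 303 above, was 184 with median centring, 400 after a further quantile normalization and 169 without the 4 arrays farthest from their group means. Array weights gave 1207 genes for D3 and 1644 for D4. The D3 count was 236, 256 or 168 without A3 control replicate 1, 2 or 4 and 237, 227 or 250 without D3 control replicate 1, 2 or 5, and the D4 count was 368 or 281 without A3 control replicate 1 or 4, while another split of the A3 and D4 arrays called 1838, so chance is not excluded for D4.

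Of these genes, 234 were called the same way in both clones, 122 higher and 112 lower, and 1 was called in opposite directions. Independent lists of these sizes would share 3.94 higher and 3.4 lower genes. Both clones were set against the same A3 arrays, and part of the excess may come from them. In 20 simulations all groups, A3 included, were drawn without differences and with noise independent between genes and arrays. There D3 and D4, set against the same simulated A3 arrays, shared 0 calls. Their correlation across genes was 0.571, their covariance 0.0090, and 69.4% of genes had the same sign. Such noise leaves out structure among the real arrays, and another split of those shared 215 genes. The observed correlation was 0.634, the covariance 0.0184, larger by 0.00943, and 68.9% of genes had the same sign. Same-numbered untreated D3 and D4 arrays were also correlated (0.214 to 0.425), which the simulations leave out; over 6 choices of D3 and D4 arrays with no number in common the covariance was 0.0126 to 0.0213. With no shared arrays, setting untreated D3 against untreated A3 and treated D4 against treated A3, 258 genes were called the same way (148 higher, 110 lower), and the reverse gave 262 (102 higher, 160 lower), with correlations of 0.535 and 0.523. These choices were made after seeing the data, and a correlation across genes does not rest on independent replicates. All of them still use the clone A3 as reference, so traits of A3 alone can also give shared calls. The shared count was 742 with array weights, 68 with only the groups compared, 147 with median centring, 132 or 91 without A3 control replicate 1 or 4, and 152 or 150 without D3 control replicate 1 or 2.

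When the resistant clones were set against the mean of both sensitive lines, 1873 genes were called, 838 higher and 1035 lower. PASD1 (1.95 ± 0.08 SE), DHRS2 (1.84 ± 0.08 SE), the tissue plasminogen activator PLAT (1.08 ± 0.06 SE), SOCS2 (0.76) and EMP2 (0.70) were the clearest on the higher side. On the lower side were TSPAN8 (-1.14 ± 0.06 SE), CHRM3 (-0.89), TCN1 (-1.33), BMPR1B (-0.93) and the potassium channel gene KCNJ6 (-0.89). The interferon list fell, with 32 of 37 genes lower and 0 higher (33 lower when adjusted over the list alone), at an adjusted p of 2.5e-35 (adjusted p = 0.0385 with an estimated correlation). Of 35 mitosis genes 14 rose (18 when adjusted over the list alone) and of 36 DNA replication genes 12 rose (19), while 11 of 31 hypoxia genes (14) and 10 of 19 sterol genes (13) fell. Their adjusted p-values were 2.3e-08, 1.1e-09, 2.3e-08 and 1.3e-09, with adjusted p = 0.514, 0.478, 0.514 and 0.142 with an estimated correlation. For the interferon, mitosis, DNA replication and hypoxia lists it was wt that stood apart: the interferon score was 0.84 in wt, -0.22 in A3, -0.27 in D3 and -0.33 in D4, the mitosis score -0.20, 0.44, 0.31 and 0.27, and the hypoxia score 0.46, -0.09, -0.21 and 0.04. Only 2 lines stand on each side, and with the line as a random block 292 genes were called, 146 in each direction.

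In CPA-treated tumours the resistant clones differed from A3 in 1402 genes, 732 higher and 670 lower. PASD1 (1.84 ± 0.09 SE), DHRS2 (1.72 ± 0.09 SE), STK26 (1.32), ZNF486 (1.28) and the amino acid transporter SLC7A6 (0.75) had the smallest adjusted p among those that were higher. GABRE (-0.98 ± 0.07 SE), CHRM3 (-0.87), HCLS1 (-1.03), NTS (-2.12) and PDE3A (-0.80) did so among those that were lower. Of 36 DNA replication genes 9 were lower and 1 was higher (17 and 2 when adjusted over the list alone), with an adjusted p of 5.5e-06 for the list and adjusted p = 0.76 with an estimated correlation. The sterol list was lower here too, with 4 of 19 genes called (6 when adjusted over the list alone) and an adjusted p of 9.9e-05, against adjusted p = 0.76 with an estimated correlation. Of 31 hypoxia genes 4 were lower (5 when adjusted over the list alone), at adjusted p 0.0105 and adjusted p = 0.76 with an estimated correlation. Without treated A3 replicate 1 the count was 738.

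A3 was also set against wt, the unpassaged line, although a single clone cannot separate passage in animals from the selection of that clone. Here 3200 genes were called, 1753 higher in A3 and 1447 lower. Of the called genes 120 were at least 2-fold lower and 12 at least 2-fold higher. Ceruloplasmin (CP), a copper-carrying plasma protein, was 20.4-fold lower (-4.35 ± 0.31 SE, adjusted p 1.9e-10) and the interferon-induced gene IFI44L was 7.07-fold lower (-2.82 ± 0.27 SE, adjusted p 2.1e-08). NTS was 5.99-fold higher (2.58 ± 0.24 SE, adjusted p 8.2e-09).

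Besides CP and IFI44L, the genes that fell most were the death ligand TNFSF10 (-2.14), the matrix protein SPARC (-2.07), SAMD9L (-2.04), XAF1 (-1.97), HSD17B13 (-1.96), SLC14A1 (-1.92), TRIM22 (-1.87), IFITM1 (-1.86), LGR5 (-1.81) and CSRNP3 (-1.78). Those that rose most after NTS were reelin (RELN, 1.55), MAGEC2 (1.55), SERPINB7 (1.48), the collagen COL12A1 (1.23), CYP2B7P (1.13), the cytidine deaminase APOBEC3B (1.12), IL13RA2 (1.08), H2AC4 (1.05), PDPN (1.04), H2BC14 (1.03) and S100A2 (1.02). NTS, MAGEC2, SERPINB7, IL13RA2 and PDPN, all higher in A3 than in wt, were among the genes that were lower in the resistant clones than in A3.

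**Figure D2:**
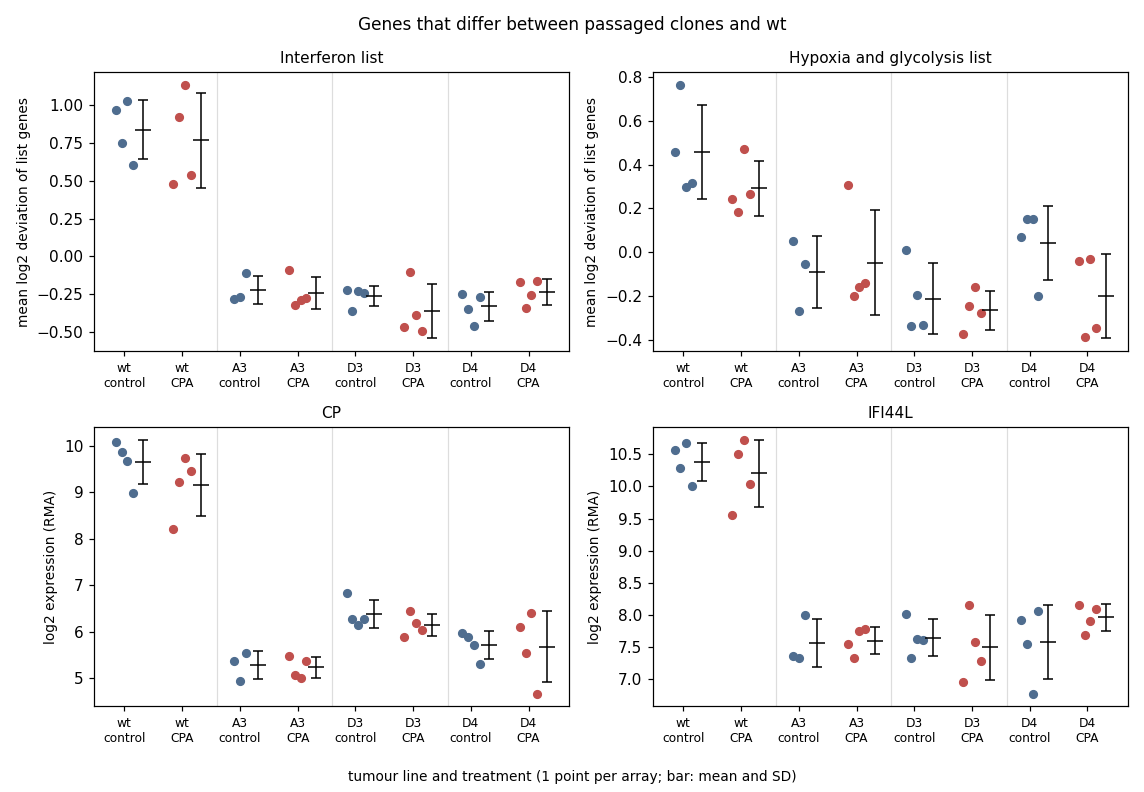
Mean log2 deviation from the mean over all arrays for the interferon list and the hypoxia and glycolysis list, and log2 expression of CP and IFI44L (vertical axes), on each array of the 8 groups (horizontal axes; blue control, red CPA; black bars mean and SD). The interferon score averaged 0.84 in untreated wt and between -0.33 and -0.22 in the 3 untreated clones, and CP averaged 9.65 in untreated wt and 5.29 in untreated A3.

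Interferon-induced genes fell as a group. Of 37 measured members 31 fell, 0 rose and 6 did not pass, and 33 fell with 1 rising when adjusted over the list alone. IFIT2 (-1.45 ± 0.15 SE), OAS2 (-1.66 ± 0.18 SE) and PARP9 (-1.29 ± 0.14 SE) were among them. The list's adjusted p was 1.8e-33, and adjusted p = 0.0318 with an estimated correlation. DNA replication genes rose, 31 of 36 with 0 falling (34 when adjusted over the list alone), as CDC45 (0.95), MCM5 (0.84) and MCM2 (0.67) did, with adjusted p 7.8e-26 and adjusted p = 0.0318 with an estimated correlation. Mitosis genes rose in 26 of 35 cases with 0 falling (30 when adjusted over the list alone), including BIRC5 (0.75, or 0.43 on its other probe set), PLK1 (0.90), KIF2C (0.84) and CDC20 (0.82), with adjusted p 9.7e-24 and adjusted p = 0.0487 with an estimated correlation.

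Genes induced by hypoxia were lower in A3. Of 31 members 16 fell and 0 rose (20 fell when adjusted over the list alone), among them LOX (-1.39), STC2 (-1.13), INSIG2 (-0.98) and P4HA1 (-0.78), with adjusted p 3.6e-12 but adjusted p = 0.241 with an estimated correlation. Of 30 stress response genes 12 fell and 2 rose (14 and 2 when adjusted over the list alone), with HERPUD1 at -0.63 and DNAJC3 at -0.76, at adjusted p 0.000144 and adjusted p = 0.241 with an estimated correlation. Of 11 prostate lineage genes 4 fell, PMEPA1 (-0.49), STEAP2 (-0.57), HOXB13 (-0.37) and FOXA1 (-0.34), or 6 when adjusted over the list alone, at adjusted p 0.0325 and adjusted p = 0.392 with an estimated correlation. In the list for repair of alkylated and crosslinked DNA 12 of 35 genes rose and 3 fell (14 and 3 when adjusted over the list alone), with PARP1 (0.52), FANCI (0.56), ERCC2 (0.50) and FANCG (0.45) rising, at adjusted p 0.0108 and adjusted p = 0.332 with an estimated correlation. Single genes moved both ways elsewhere: E-cadherin (CDH1) fell by 1.03 and the receptor kinase AXL rose by 0.71.

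No host-cell list was called between A3 and wt, but members changed in both directions. The collagen genes COL5A2 (-0.72) and COL3A1 (-1.01) and the endothelial receptor KDR (-1.19) fell, and COL6A3 (0.42) and ROBO4 (0.40) rose. A fit of only these 2 groups called 1882 genes.

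CPA was compared with control within each line, to see which genes the drug moved in sensitive and in resistant tumours. Of 35 mitosis genes 5 fell after CPA in wt, 14 in A3, 15 in D3 and 6 in D4, where the list as a whole had adjusted p = 0.569 with an estimated correlation. KIF20A, a mitotic kinesin, was 2.00-fold lower in wt (-0.998 ± 0.11 SE), 2.71-fold lower in A3 (-1.44 ± 0.11 SE), 2.43-fold lower in D3 (-1.28 ± 0.11 SE) and 2.16-fold lower in D4 (-1.11 ± 0.11 SE), with adjusted p-values of 1.7e-06, 3.0e-09, 7.6e-09 and 2.4e-07. The mitotic kinase PLK1 fell by 0.93, 1.26, 1.10 and 0.96 in the same order, and cyclin B1 (CCNB1) by 0.65, 1.04, 0.97 and 0.78. The genes called lower in all 4 lines were 6: BUB1, CCNB1, CDC20, DHRS2, KIF20A and PLK1.

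**Figure D3:**
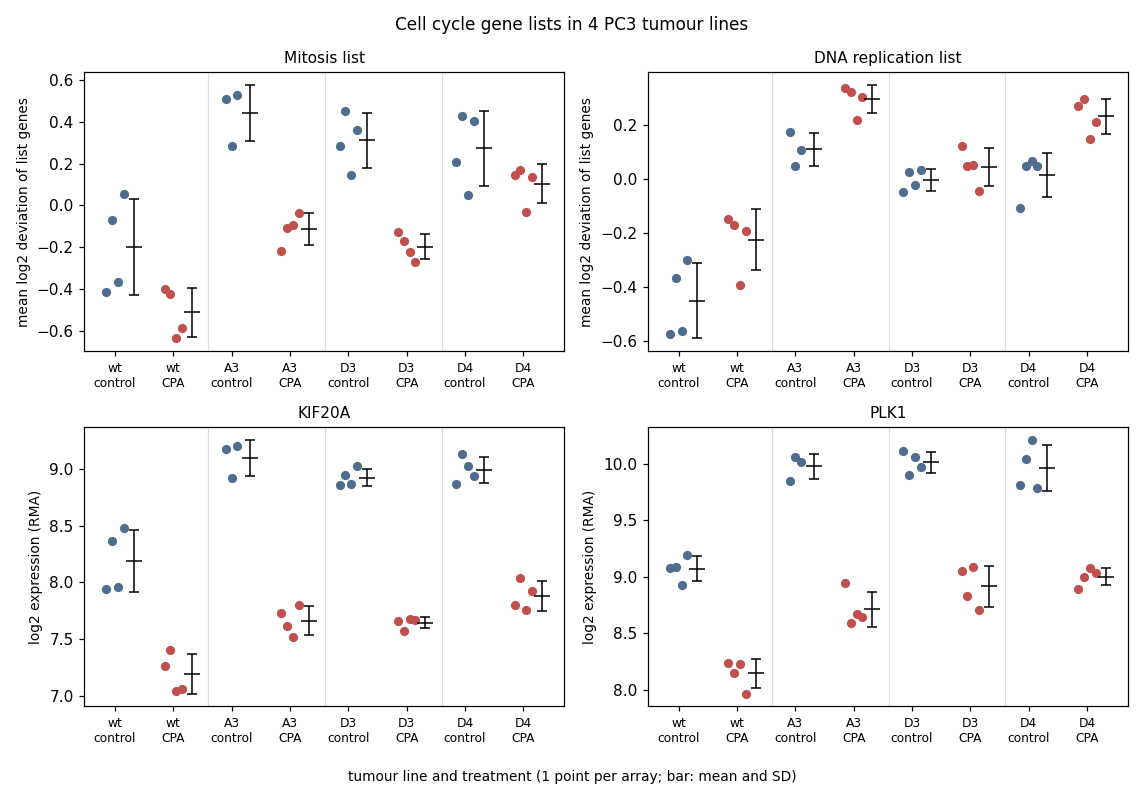
Mean log2 deviation from the mean over all arrays for the mitosis and DNA replication lists, and log2 expression of KIF20A and PLK1 (vertical axes), on each array of the 8 groups (horizontal axes; blue control, red CPA; black bars mean and SD). KIF20A averaged 9.10 in untreated and 7.66 in treated A3, and the mitosis score averaged 0.44 in untreated A3, -0.11 in treated A3, 0.27 in untreated D4 and 0.10 in treated D4.

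In wt 8 genes were called, 1 higher and 7 lower. POLA2, a subunit of DNA polymerase alpha, rose (0.42 ± 0.08 SE, adjusted p 0.0401), and GAS2L3 (-0.64), DHRS2 (-0.56), BUB1 (-0.48) and CDC20 (-0.48) fell along with KIF20A, PLK1 and CCNB1. Of 35 mitosis genes 5 fell (14 when adjusted over the list alone), at an adjusted p of 8.5e-37 for the list and adjusted p = 0.0113 with an estimated correlation. Of 36 DNA replication genes 1 rose, but 19 rose when adjusted over the list alone, with CDC45 at 0.43, at adjusted p 9.7e-30 and adjusted p = 0.0113 with an estimated correlation. Of 35 repair genes none was called and 4 rose when adjusted over the list alone, with a median of 0.10, at adjusted p 1.2e-09 and adjusted p = 0.0113 with an estimated correlation.

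Other lists were called in wt with no member passing by itself. Hypoxia genes had a median of -0.16 (adjusted p 1.2e-07), sterol genes -0.09 (0.000173, with 2 lower when adjusted over the list alone), mesenchymal genes -0.05 (0.00514), interferon genes -0.07 (0.0169), neuroendocrine markers -0.10 (0.0315) and glutathione genes 0.06 (0.0169). With an estimated correlation their adjusted p-values were 0.357, 0.357, 0.233, 0.725, 0.357 and 0.357. Of the host-cell lists, fibroblast markers were lower by a median of 0.05 (adjusted p 0.0232, and adjusted p = 0.27 with an estimated correlation) and adipocyte markers by 0.07 (adjusted p 0.0169, and adjusted p = 0.357 with an estimated correlation). Chance is not excluded for the count in wt, as another split of the arrays called 9 genes. A further centring on the array medians left 0 higher and 3 lower genes in wt, and without any of 5 arrays in turn (control replicates 2 and 3, CPA replicates 1, 2 and 5) the count was 3 or 5.

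In A3 61 genes were called, 18 higher and 43 lower, and 7 of the lower ones fell at least 2-fold. Besides KIF20A and PLK1 the lowest were the kinetochore motor CENPE (-1.41 ± 0.23 SE), DEPDC1 (-1.33 ± 0.28 SE), HMMR (-1.17 ± 0.22 SE), DLGAP5 (-1.06), CCNB1, the histone genes H2BC14 (-0.94), H1-3 (-0.89) and H2BC7 (-0.87), the kinase AURKA (-0.88) and FAM83D (-0.79). The highest were RIBC2 (0.68 ± 0.10 SE), the exonuclease EXO1 (0.56 ± 0.13 SE), CDC6, which licenses replication origins (0.55 ± 0.12 SE), the recombination gene RAD54L (0.49), POLA2 (0.47), DNAJC22 (0.47), DONSON (0.47), CLPS (0.44), E2F7 (0.44), SLC1A4 (0.43), POGLUT3 (0.41) and TMEM106C (0.40). Of 35 mitosis genes 14 fell (25 when adjusted over the list alone; adjusted p 7.2e-53, and adjusted p = 0.00282 with an estimated correlation). Of 36 DNA replication genes 3 rose and 0 fell (9 when adjusted over the list alone), at adjusted p 7.3e-14 and adjusted p = 0.202 with an estimated correlation.

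The repair list (1 of 35 genes called, 3 when adjusted over the list alone) had a median of 0.10 in A3, at adjusted p 0.000254 and adjusted p = 0.202 with an estimated correlation. Sterol genes had a median of -0.11 (adjusted p 0.00318, and adjusted p = 0.553 with an estimated correlation) and ribosomal protein genes, a control list, -0.09 (adjusted p 0.000213, and adjusted p = 0.467 with an estimated correlation). Endothelial markers were higher by a median of 0.10 (adjusted p 0.0423, and adjusted p = 0.467 with an estimated correlation), with no member called. A further quantile normalization gave 29 higher and 42 lower genes in A3, and median centring 8 and 35. Without A3 control replicate 4 or 1 the count was 18 or 26, without A3 CPA replicate 3 or 4 it was 38, a fit of only these 2 groups called 15, array weights gave 177 and leaving out the 4 arrays farthest from their group means 129.

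In D3 40 genes were called, all of them lower, and by limma 2210 genes in either direction had an unadjusted p under 0.05. After KIF20A and PLK1 the lowest were HMMR (-1.01 ± 0.21 SE), CCNB1, CENPE (-0.97 ± 0.21 SE), AURKA (-0.92 ± 0.12 SE), DHRS2 (-0.88 ± 0.11 SE), DLGAP5 (-0.87), H2BC7 (-0.86), H1-3 (-0.84), H2BC14 (-0.80) and cyclin B2 (CCNB2, -0.78). Of 35 mitosis genes 15 fell (25 when adjusted over the list alone), at adjusted p 1.7e-40 and adjusted p = 0.0125 with an estimated correlation. No other list was called in D3. The DNA replication list had a median of 0.07 and an adjusted p of 0.268, with 0 genes called and 1 in each direction when adjusted over the list alone. No gene was called higher, and CRYBB3 (0.34), ZNF69 (0.50) and LINC01260 (0.44) had the smallest p, with adjusted p-values of 0.0547, 0.056 and 0.0689. Without D3 control replicate 2 the count was 24, without CPA replicate 5 it was 26, and with array weights 185.

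In D4 178 genes were called, 115 higher and 63 lower. Of the lower genes 22 were also called lower in A3, 20 in D3 and 6 in wt. The lowest were KIF20A, PLK1, DHRS2 (-0.95 ± 0.11 SE), CCNB1, CDC20 (-0.68 ± 0.09 SE), AURKA (-0.64) and the histone genes H2BC14 (-0.94), H2AC4 (-0.87), H4C3 (-0.74), H4C2 (-0.74), H1-3 (-0.73) and H3C10 (-0.65). The highest were ZNF681 (1.04 ± 0.20 SE), the Fanconi anaemia gene FANCB (0.95 ± 0.23 SE), MND1 (0.95 ± 0.16 SE), the helicase BRIP1 (0.90 ± 0.20 SE), ZNF682 (0.87), C5orf34 (0.81), LRRCC1 (0.80), ATAD5 (0.78), CEP162 (0.76), HOOK1 (0.75), cyclin E2 (CCNE2, 0.75) and OR8G2P (0.74). Of 35 repair genes 8 rose and 0 fell (14 when adjusted over the list alone), with BRCA1 at 0.74 and FANCI at 0.51, at adjusted p 6.3e-08 and adjusted p = 0.0526 with an estimated correlation. Of 36 DNA replication genes 3 rose, POLA2 (0.38), RRM2 (0.51) and CCNE2, or 21 when adjusted over the list alone, at adjusted p 7.5e-11 and adjusted p = 0.515 with an estimated correlation. Of 35 mitosis genes 6 fell (13 when adjusted over the list alone), at adjusted p 0.000165 and adjusted p = 0.569 with an estimated correlation.

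Hypoxia genes had a median of -0.18 in D4 with no member called (adjusted p 0.00197, and adjusted p = 0.569 with an estimated correlation), and neuroendocrine markers -0.20 with 2 lower when adjusted over the list alone (adjusted p 0.0407, and adjusted p = 0.569 with an estimated correlation). All host-cell lists also had medians under 0 in D4, from -0.20 for muscle to -0.08 for myeloid markers, and skin had the smallest adjusted p (0.0925). No line had the list of p53 targets called under CPA. Untreated D4 replicates 1 and 4 were among the arrays farthest from their group mean, and without these and the 2 other arrays farthest from theirs 9 genes were called, 0 higher and 9 lower, a check chosen after seeing the data. Median centring gave 199 higher and 54 lower genes, array weights 349 in all and a fit of only these 2 groups 17, and the count was 34 without D4 control replicate 1, 49 without replicate 4, 787 without replicate 2, 366 without replicate 5, and 35, 41 or 54 without CPA replicate 1, 2 or 5.

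The lines shared lower genes under CPA. A3 and D3, which have no array in common, shared 30 lower genes where independent lists would share 0.0993, and D3 and D4 shared 20 where 0.146 would be shared. Over all genes, however, the CPA effects correlated at 0.467 between A3 and D3 but at -0.365 between D3 and D4 and -0.0867 between A3 and D4, values that do not rest on independent replicates. Lower in A3, D3 and D4 alike were 19 genes, which besides the 6 above were AURKA, CCNF, FAM83D, GTSE1, PTTG1 and the histone genes H1-3, H2AC15, H2AC20, H2AC4, H2BC14, H2BC3, H2BC7 and H4C2. A3 and D4 shared 8 higher genes where independent lists would share 0.12, among them POLA2, RAD54L, EXO1, DONSON and RIBC2.

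Whether CPA acted differently in resistant and sensitive lines was tested directly, as the mean CPA effect in D3 and D4 minus that in wt and A3. Only the keratin gene KRT73 was called (-0.48 ± 0.08 SE, adjusted p 0.0373), and 406 genes had an unadjusted p under 0.05 by limma. KRT73 changed by 0.20 in wt, 0.34 in A3, -0.14 in D3 and -0.29 in D4, of which none was called within its line. The sterol list was higher in this difference (median 0.10, 17 of 19 genes above 0), with adjusted p 6.3e-06 and adjusted p = 0.953 with an estimated correlation. The DNA replication list was lower (median -0.08, 33 of 36 genes below 0; adjusted p 0.000838, and adjusted p = 0.999 with an estimated correlation), and the mitosis list was higher (median 0.04; adjusted p 0.0197, and adjusted p = 0.999 with an estimated correlation). No member of these 3 lists was called, also when adjusted over the list alone, and a gene past the threshold in 1 line and not in another is not thereby shown to differ. KRT73 lost its call with the replicate number as a block, with a variance trend, with array weights, on all probe sets and without the 4 arrays farthest from their group means, and it was itself among the dimmest 30% of genes. Leaving out 1 array gave 0 called genes unless it was wt control replicate 1 or 2, A3 control 2 or 4, D3 control 2, D3 CPA 5, D4 control 2 or D4 CPA 1, and chance is not excluded (7 of 100 splits called as many).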

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

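Only the comparison of the CPA effect between lines was planned; the tests of arrays that stand apart and of dividing cells, and the counts over other splits of the arrays, were written down after the results they bear on had been seen. Among 112 groups of 4 arrays checked (16 values in 7 groups), 6 held an array far from the others, and chance alone gives about 1 in 20. CPA-treated D4 replicate 4 lay at -5.83 on the second principal component against -20.8 to -18.3 for the other D4 arrays of its group (gap over range 0.835). List scores in this part also have the median deviation of each array removed, unlike those plotted above. The mitosis score of CPA-treated D4 replicate 4 was then -0.02 against 0.16 to 0.19 (0.893), but without that step the gap over range was 0.826, under Dixon's bound for 4 arrays. The interferon score of untreated D3 replicate 2 was -0.37 against -0.24 to -0.23 (0.945, or 0.869 without that step), and the sterol synthesis score of untreated D4 replicate 5 was -0.24 against -0.0318 to -0.0283 (0.984), or -0.24 against -0.0403 to 0.0149 (0.784, also under the bound) without that step. PASD1 was at 7.53 in CPA-treated D4 replicate 2 against 7.31 to 7.34 (0.844), and KIF20A at 7.57 in CPA-treated D3 replicate 3 against 7.66 to 7.67 (0.873).

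In the comparison of the CPA effect between resistant and sensitive lines KRT73 was called by limma (-0.48, adjusted p 0.0373). The count moved in 23 of 31 runs that left out 1 array, and chance is not excluded (7 of 100 splits called as many). At the preset correlation only, 3 lists also passed: sterol synthesis (median 0.10), DNA replication (median -0.0786) and mitosis (median 0.0389). With an estimated correlation their adjusted p-values in camera were 0.953, 0.999 and 0.999.

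CPA lowered the mitosis list in each line at the preset correlation, though its score did not pass an exact permutation test in wt (-0.317, p 0.0857) or in D4 (-0.134, p 0.229; -0.169 and 0.2 without removing array medians). Fewer dividing cells in the treated tumours may be expected to lower the DNA replication list too. Between the untreated clones and wt the 2 scores differed alike (0.532 and 0.612 in A3, 0.434 and 0.496 in D3, 0.435 and 0.442 in D4). These lines also differ in many other genes, so the expectation is only a rough guide. The replication score instead changed by 0.22 ± 0.10 (SE between arrays, exact permutation p 0.0857) in wt, 0.19 ± 0.05 in A3, 0.04 ± 0.04 in D3 and 0.25 ± 0.06 in D4. It moved above the mitosis score by 0.538 ± 0.057 in wt, 0.741 ± 0.077 in A3, 0.556 ± 0.056 in D3 and 0.387 ± 0.096 in D4 (exact permutation p 0.0286 each, two-sided, the smallest these groups allow). If the expectation holds, this argues against fewer dividing cells as the whole cause. In wt and D4 it says less, as the mitosis score itself did not pass there. The score of the replication-dependent histone genes, described below and picked after the data had been seen, went the other way. It changed by -0.181 in wt, -0.359 in A3, -0.336 in D3 and -0.338 in D4 (exact permutation p 0.0286 each). Fewer dividing cells may be expected to lower these genes too, so the question stays open. The 4 arrays that stand apart do not account for the lower mitosis list at the preset correlation. Without them the list was lower in every line at an adjusted p of at most 2.4e-20. Its score changed by -0.637 ± 0.047 in A3 (-0.546 ± 0.102 with all arrays), -0.485 ± 0.072 in D3 (-0.514 ± 0.075) and -0.299 ± 0.052 in D4 (-0.134 ± 0.113), while wt lost no array. With an estimated correlation, which rose from 0.401 to 0.473, the adjusted p in A3 went from 0.00282 to 0.0531 with 2 control arrays left. It was 0.0192 in wt, 0.0184 in D3 and 0.215 in D4. A hold-up of cells before mitosis may be the biological reading, which no test here separates from other changes in the cycle.

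The 115 genes called higher under CPA in D4, among them ZNF681, FANCB and BRIP1, could come from untreated D4 arrays 1 and 4 that stand apart. Without these 8 genes were called, 0 higher and 8 lower, whereas without untreated replicates 2 and 5 there were 2334, 1416 higher and 918 lower. Any 2 arrays left out also cost precision: the other 4 pairs left between 8 (replicates 4 and 5) and 62 (2 and 4) higher genes, with 18 (1 and 2) and 16 (1 and 5) between. The pair was picked because it stood apart, and a real difference between tumours of this clone is not excluded. No biological explanation was tested.

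Other splits of the same arrays were counted for each comparison, with 35 splits of 7 or 8 arrays and otherwise 100 drawn ones, the real one included in both. For the resistant clones against A3, 2 of 100 splits called as many as 673 genes, with at most 2476 in another. That share is under 0.05, but it rests on 100 drawn splits, and D4 against A3 did not pass by itself. Chance is therefore not firmly excluded there. Chance in the grouping of single arrays is excluded at a share under 0.05 for D3 against A3 (1 of 35, 393 against at most 25). The same holds for the genes shared by D3 and D4 (1 of 100, 234 against 215). For resistant against sensitive lines no other split called as many (1 of 100, 1873 against 1280). Single arrays were moved there, so this shows only that the lines differ. With 2 lines a side it cannot exclude a chance division of the lines, and the line as a random block gave 292 genes. Chance in the grouping of single arrays is also excluded for the resistant clones against A3 under CPA (1 of 100, 1402 against 244) and for A3 against wt (1 of 35, 3200 against 1800). So it is for CPA in A3 (1 of 35, 61 against 16), D3 (1 of 35, 40 against 1) and D4 (1 of 35, 178 against 2). Chance is not excluded for D4 against A3, where 2 of 35 splits gave as many as 653 genes and the highest other gave 1838, nor for CPA in wt (2 of 35, 8 against 9), nor for the CPA effect between resistant and sensitive lines (7 of 100, 1 against 4002). The split with 1838 genes set A3 replicate 2 and D4 replicates 1 and 4 against the other untreated A3 and D4 arrays. Such splits, calling several times the real count, point to a structure of the samples that the groups do not hold: the leading component of the deviations from the group means carried 27.7% of them, and A3 replicate 2 (0.39) and D4 replicates 1 (0.24) and 4 (0.23) lay on the same side of it. The interquartile range of the values on an array went partly with this. It was 2.79 on A3 replicate 2 against 2.98 and 2.97 on A3 replicates 1 and 4, and 2.68 on D4 replicate 1. On D4 replicate 4 it was 2.87, between 2.94 and 2.82 on D4 replicates 2 and 5. Whether array or RNA quality lies behind the structure was not tested.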

How the results depend on the processing

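No named gene or list that was called reversed its direction under the alternatives run on it, apart from wt in place of A3. Under that, 12 of the 62 genes named for the resistant clones were called the opposite way. The scores of mitosis and DNA replication, lower than in A3, were higher than in wt by 0.434 to 0.496 in D3 and D4. The stress response list, higher than in A3, was lower than in wt (median -0.18 in D3 and -0.25 in D4). Ribosomal protein genes, lower in D4 than in A3, had a median of 0.04 against wt without a call. The alternatives without the 4 arrays that stand apart and without shared arrays, and the genes named for the resistant clones set against wt, were chosen after seeing the data. Where a count moved by over 1.5 times the cause was not tested, except that a fit of fewer groups or arrays leaves fewer degrees of freedom.

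A fit of only the groups compared gave 237 genes for the resistant clones against A3, 105 for D3, 67 for D4, 68 shared by both, 1882 for A3 against wt, and 2, 15 and 17 for CPA in wt, A3 and D4. Array weights gave 1782 for the resistant clones against A3, 1207 for D3, 1644 for D4, 742 shared by both, 177, 185 and 349 for CPA in A3, D3 and D4, and 0 for the CPA effect between resistant and sensitive lines. That last count, 1 gene, was also 0 with the replicate block, a variance trend, on all probe sets, without dim genes (a filter that removes the gene itself) and without the 4 arrays. Median centring gave 147 shared genes for D3 and D4 and 3 for CPA in wt, all probe sets gave 5 there, and wt in place of A3 gave 2293 shared genes. With the line as a random block resistant against sensitive lines gave 292. Without the 4 arrays that stand apart CPA gave 13 genes in wt, 129 in A3 and 9 in D4.

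Leaving out each array in turn gave 268 (without A3 control replicate 4) to 819 (D4 control 4) for the resistant clones against A3, 168 (A3 control 4) to 272 (D3 control 3) for D3, 281 (A3 control 4) to 799 (D4 control 4) for D4, and 91 (A3 control 4) to 261 (D4 control 4) for genes shared by both. For D3 the count was 236, 256, 237, 227 and 250 without A3 control 1 or 2 or D3 control 1, 2 or 5. For D4 it was 368, and for the shared genes 132, without A3 control 1, with 152 and 150 shared without D3 control 1 and 2. The other ranges were 738 (A3 CPA 1) to 1427 for the CPA-treated arm, 3 to 10 for CPA in wt, 18 to 61 in A3, 24 to 39 in D3, 34 to 787 in D4, and 0 to 1 for the effect between lines. Resistant against sensitive lines (1414 to 2119) and A3 against wt (2442 to 3009) stayed within 1.5 times.

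The replicate numbers do not pair the samples throughout: of 28 pairs of groups only 2 had every same-numbered pair of arrays correlated above 0.1, untreated wt with D3 and untreated D3 with D4, and neither set control against CPA. With the replicate block the counts were 574 for the resistant clones against A3, 324 for D3, 573 for D4, 189 shared by both, 1798 for resistant against sensitive lines, 1191 for the CPA-treated arm, 3002 for A3 against wt, and 5, 61, 50 and 169 for CPA in wt, A3, D3 and D4. Of list calls at the preset correlation, 10 were kept and 47 lost with an estimated one. Of named gene calls, 50 of those tested were lost without the 4 arrays, 81 with only the groups compared and 21 with median centring. Signal over background was not examined, and dim genes are limited by it.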

Other observations

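The comparisons in this part, between D4 and D3 and of D3 and D4 with wt, and the tests of histone and neighbouring genes were all chosen after the data had been seen. The resistant clones differed from each other in 56 genes, 16 higher in untreated D4 and 40 lower. Same-numbered arrays of these 2 groups were correlated, and the replicate number as a block gave 65 genes, while a fit of only these 2 groups gave 22, or 17 with the block. F3 (1.52 ± 0.15 SE), PSG3 (0.75), PRSS35 (0.74), SRGN (0.72) and MAGEC2 (0.68) were higher in D4. ANKRD30A (-1.59 ± 0.14 SE), ZNF711 (-1.67 ± 0.18 SE), the endothelial proteoglycan gene ESM1 (-1.11), the adhesion gene NCAM2 (-1.01) and SERPINB7 (-0.98) were lower.

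The low interferon level was shared by the 3 passaged clones. D3 differed from untreated wt in 3132 genes, or 3174 with the replicate number as a block and 2605 with the block in a fit of only these 2 groups. Against untreated wt, 33 of 37 interferon genes fell in D3 and 33 in D4, with medians of -1.16 and -1.23 and an adjusted p of 0.0212 and 0.0211 with an estimated correlation. IFI44L stood at -2.74 in D3 and -2.81 in D4 against wt on the log2 scale, and CP at -3.26 and -3.93. DNA replication genes rose in both, 33 of 36 in each, with medians of 0.46 and 0.47, but adjusted p = 0.0615 and 0.0878 with an estimated correlation. Hypoxia genes fell in 21 of 31 cases in D3 and in 13 in D4 (adjusted p = 0.141 and 0.503 with an estimated correlation).

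Histone genes fell under CPA in numbers that no fixed list covered. All 54 measured genes of the H1, H2A, H2B, H3 and H4 clusters, picked by their symbols, were examined. None was called in wt, 13 fell in A3, 9 in D3 and 15 in D4, and none rose. Their medians were -0.16, -0.35, -0.30 and -0.39. The hypothesis that they fall as a group came from calls in A3, D3 and D4, so only wt, with other arrays and no call, can test it: there 51 of 54 were lower, with a p of 0.000547 with an estimated correlation. Such a fall may be shared by the group, but these genes are near copies and their probe sets may read each other's RNA, so that the 54 are not independent readings.

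Some neighbouring genes differed together between the resistant clones and A3. Over windows of 30 genes in chromosome order, 16 runs differed between the resistant clones and A3, untreated, by more than the largest window mean of 100 shuffled orders (0.166), 9 of them higher and 7 lower. These numbers depend on the draw of shuffled orders: over 10 draws the bound ran from 0.159 to 0.207, the number of runs from 4 to 19 and the length of the run on chromosome 16 described next from 56 to 113 genes. Besides that run, 3 others had a window mean past the highest of these bounds: TM6SF2 to TDRD12 (0.323) and TSPAN16-AS1 to JUNB (0.218) on chromosome 19, and CNOT2 to NR2C1 (-0.296) on chromosome 12, against 0.267 for the run on chromosome 16. The medians of these 3 over the whole run were smaller in size (0.09, 0.02 and -0.14, against 0.18 on chromosome 16), and 74.6%, 58% and 16% of their genes were higher, so the mean alone overstates how evenly the genes of the 2 runs on chromosome 19 moved. In those 2 runs untreated A3 lay lowest, below wt too. From TM6SF2 to TDRD12 the mean levels were 0.05 in wt, -0.17 in A3, 0.08 in D3 and -0.04 in D4. From TSPAN16-AS1 to JUNB they were 0.08, -0.15, -0.004 and -0.06 in the same order. In the runs on chromosome 22 untreated A3 stood highest, between 0.11 and 0.13, above wt as well as D3 and D4. These runs thus set A3 apart from wt as well. In the draw used, the longest lay on chromosome 16 from RIPOR1 to C16orf46, with 110 genes of which 91.8% were higher and 29 called, and it was followed by another from ATP2C2 to PRDM7 with 67 genes, 92.5% higher. Its mean level was -0.14 ± 0.01 (SD, n = 4) in wt, -0.09 ± 0.01 (SD, n = 3) in A3, 0.07 ± 0.02 (SD, n = 4) in D3 and 0.13 ± 0.05 (SD, n = 4) in D4, relative to the mean over all arrays.

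A regional trend of single arrays is argued against by the CPA-treated arrays, which had no part in finding the run: there D3 lay above A3 by 0.171 ± 0.018 (SE) and D4 by 0.27 ± 0.015 (SE), each with an exact permutation p of 0.0286, two-sided, the smallest that 4 arrays a side allow. A few regulated genes are argued against by the 81 genes without a call, which were still higher by 0.145 in D3 and 0.189 in D4 on those arrays. A loss in A3 is argued against by wt, which lay at -0.0497 relative to A3 and so below it. A gain of the segment shared by D3 and D4 may explain the run, since at least 81.8% of its genes were higher in each clone on the treated arrays, just past a bound of 80% set after the data had been seen. DNA was not measured here, so this stays a hypothesis.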
